A study of Mus musculus with 4 samples.

How the data were processed

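Gene expression was measured in Vα14i natural killer T (NKT) cells sorted from mouse liver. Per the labels' protocols, mononuclear cells were isolated from perfused livers of C57Bl/6 mice aged about 2 months, cells carrying CD19, TER-119, CD11b or CD62L were depleted with magnetic beads, and cells binding both CD1d tetramers loaded with the lipid PBS57 and an antibody to the TCR β chain were sorted. Each sample was a pool of cells from 3 mice, and 4 pools from 12 mice were hybridised, 1 per array. Biotinylated cRNA was made from 200 ng of total RNA and hybridised, per the labels, to Affymetrix 430 2.0 mouse expression arrays.

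The deposited values were linear signal intensities, 1 per probe set, and the submitters' processing notes name MAS5. The version and settings of MAS5, and its detection calls, are not given in the sources used here. The deposited values had the same 2% trimmed mean, 2500.02, on each of the 4 arrays, so the arrays had been scaled to a common level before deposit and no further scaling was applied. This scaling assumes that total mRNA per array was alike, and a change in total mRNA content would not be seen. Every column of the table was used.

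The table held 45101 probe sets, of which 64 were Affymetrix controls. The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, the controls included. Of the probe sets with 1 symbol, 34754 had a gene identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had changed there. Probe sets with several symbols or none are unnamed here and entered no gene result. Some genes of interest, among them Rorc, Il17f, Il22, Il23r, Stat1, Lck, Sell and Tcf7, had no probe set with a single symbol and were not analysed here. No genome build is named for these values, so no gene positions are given.

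Signals were transformed to log2(signal + 250), the pseudocount being 0.1 times the trimmed mean. Probe sets with a mean signal of at least 1000 over the 4 arrays (0.4 times the trimmed mean) were kept, which left 15120 probe sets, or 33.6%. For each gene the kept probe set with the highest mean signal was tested, giving 8313 of the 18193 genes with a named probe set. Fold changes are on the log2(signal + 250) scale, which understates changes of weak signals. Where a group had signals near background the size of a change depends on the pseudocount, and sizes at a pseudocount of 5 times less and 3 times more are given for the leading genes. All errors on fold changes are standard errors, and all errors on signals are standard deviations over the 2 arrays of a group.

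The 2 hd/hd arrays were compared with the 2 control arrays (1 hd/+ and 1 +/+ pool, which the labels treat together as controls) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Each moderated test had 8.74 degrees of freedom. The 2 arrays of a group came from separate pools of mice, so the spread includes differences between pools, but 2 arrays per group limit the precision. A total of 24 gene lists were fixed, and the 21 with at least 5 measured genes were tested with camera, a test in limma that compares the genes of a list with the other genes, at a preset correlation between genes of 0.01, and again with an estimated correlation. The preset takes genes as nearly uncorrelated, while 4 arrays give only an imprecise estimate of the correlation. Missing the threshold with the estimate is thus no evidence that a list did not shift. The fry test of limma, which asks whether the genes of a list move one way on balance, was run as well. All adjusted p-values in the text are from limma, camera or fry.

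The named genes were Zbtb7b, Cd4, Cd8a and Cd8b1, the 12 genes with the smallest p in each direction among those past the threshold and changed the same way in both age-matched pairs, and up to 4 measured genes with the smallest p in each list. This rule, the lists, the tests named above and the alternatives except 2 were chosen before the data were examined, but 4 of the 7 tests of explanations in the closing section were chosen after the results were seen. Ikzf2 and Nfil3, a further 11 genes (Tbx21, Zbtb16, Ccr6, Il1r1, Epas1, Arg1, Ret, Cd83, Anxa1, Abcb1a and Igha) and the sex-linked genes Xist, Eif2s3y, Kdm5d and Uty were named after their values were seen, as were members of the marker lists given only by their signals.

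The labels match each hd/hd pool to a control pool by age, as pair A (hd/hd with hd/+) and pair B (hd/hd with +/+). They name no shared litter, day or batch, and the comparison was made without the pair as a block. Fold changes were also taken within each pair, with no test since each pair has 1 array per genotype. Alternatives covered the pair as a block, quantile normalisation, median centring, the pseudocount, the filter on low signals, the choice of probe sets, the variance model, the threshold and leaving out each array in turn.

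The limma procedure was tested on simulated arrays of 8313 genes, of which 200 were changed, 50 at each size, over 20 runs. The gene means were real, but variances were drawn around the fitted intensity trend as limma assumes, with independent normal errors. It recovered 8.4% of genes changed 1.5-fold, 63.4% of those changed 2-fold, 98.4% of those changed 4-fold and 100% of those changed 8-fold. On average 5.4% of the calls were false, and the median number of calls with no changed gene was 0. These figures hold under the assumptions of limma and do not show its error rate where genes or pools vary together. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.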

Results

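The data were 4 Affymetrix expression arrays of sorted liver Vα14i NKT cells, T cells with an invariant receptor that recognises lipids presented by CD1d. The comparison asked how loss of Th-POK, the zinc finger transcription factor encoded by Zbtb7b that directs thymocytes to the CD4 lineage, alters gene expression in these cells. The hd allele carries a missense mutation in Zbtb7b, and hd/hd mice lack functional Th-POK. A pair of arrays came from hd/hd pools (A and B), and a pair from controls, with hd/+ as control A and +/+ as control B. Each pool held cells of 3 mice, so each group had 6 mice on 2 arrays. Median signals over all probe sets were 325.3 (hd/hd A), 263.5 (hd/hd B), 280.4 (hd/+) and 321.9 (+/+), and between 32.76% and 34.63% of probe sets per array had a signal above 1000. The ratio of 3' to 5' actin signals, a measure of RNA integrity, ran from 1.236 to 1.316.

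The CD8 coreceptor genes were strongly raised in hd/hd cells, while the mutated gene itself was still transcribed. Cd8a, which encodes the CD8 α chain, had signals of 47778 and 51063 on the hd/hd arrays against 392.4 in hd/+ and 361.2 in +/+. Cd8a rose by 6.31 ± 0.15 on the log2(signal + 250) scale (limma adjusted p = 1.6e-07), and by 5.48 to 6.86 over the pseudocounts tried, since its control signals lay near background. Cd8b1, which encodes the CD8 β chain, rose from 425 ± 38.5 to 7698 ± 366 (SD, n = 2; log2 3.56 ± 0.20, 2.85 to 4.03 over the pseudocounts tried, limma adjusted p = 6.59e-05). Cd4 had signals of 66.0 and 17.6 on the hd/hd arrays, 590.4 in hd/+ and 2740 in +/+, and its mean lay below the signal filter. In a fit without the filter its log2 fold change was −2.45, with a limma adjusted p of 0.214 over 18193 genes, so the fall did not pass the test. Both hd/hd signals still lay below both control signals, and the difference between both controls added to the spread. Zbtb7b signals were 2872 ± 80.5 in hd/hd and 3390 ± 105 in controls (log2 −0.22 ± 0.17, limma adjusted p = 0.669). Because hd is a missense allele, the Zbtb7b signal does not check the genotype labels. Of the 16 measured CD4 and CD8 lineage genes, Cd8a and Cd8b1 rose and 14 did not pass the test. Among these were Runx3, a CD8 lineage factor (log2 0.78 ± 0.21, adjusted p = 0.0933), and Tox, a factor needed for CD4 lineage development (−0.76 ± 0.30, adjusted p = 0.266). The median of this list was −0.11 and its mean 0.53, a difference in sign, and camera found no shift (adjusted p = 0.322). The count adjusted over the list alone was 3 higher and 0 lower.

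Over all genes, 306 of 8313 (3.68%) differed between hd/hd and control, 196 higher and 110 lower in hd/hd. The higher genes included the largest changes. On the log2(signal + 250) scale, 161 rose and 66 fell at least 2-fold, 69 rose and 6 fell at least 4-fold, and 31 rose and 1 fell at least 8-fold. After Cd8a, the genes with the smallest p among those higher were Npl, an enzyme of sialic acid breakdown (log2 4.65 ± 0.23, 3.43 to 5.91 over the pseudocounts tried), Cd8b1, Vim, the intermediate filament vimentin (4.42-fold, log2 2.14 ± 0.14), and Mycn, a transcription factor of the MYC family (log2 3.90 ± 0.26, 2.63 to 5.44 over the pseudocounts tried). They were followed by Abhd15 (5.69-fold), the potassium channel gene Kcnk1 (log2 4.52 ± 0.35, 3.48 to 5.55 over the pseudocounts tried), Gclc, whose product catalyses the first step of glutathione synthesis (4.52-fold), Gzma, Il17re, Ncoa7 (3.45-fold) and Ltb4r1. The gene with the smallest p among those lower was Il4, followed by Myo6, an unconventional myosin (2.86-fold lower), and the protease inhibitor genes Ctla2a (4.12-fold lower) and Ctla2b (3.22-fold lower), which are close paralogs. Next came the inhibitory receptor gene Btla (3.48-fold lower), Mmp9 (2.70-fold lower), the aquaporin gene Aqp9 (2.78-fold lower), Tspan32 (2.69-fold lower), Ptpn13 (log2 −2.14 ± 0.26), Rcbtb2 (3.74-fold lower), Plac8 and Atp8a2 (2.81-fold lower). Weaker kept probe sets of Tspan32 (log2 −0.62, limma adjusted p = 0.527 among probe sets) and Rcbtb2 (−1.01, 0.226) did not pass. Those of Myo6 (−1.42, 0.0823) and Mmp9 (−1.47, 0.056) fell by about as much as the tested ones but missed the threshold. The limma adjusted p of the 24 genes with the smallest p, 12 in each direction, ran up to 0.00283. The 24 were chosen among genes that moved the same way in both age-matched pairs. All 306 did so, but the test passes genes with little spread within groups, which favours this outcome. The count was sensitive to single arrays. It was 122 without hd/hd A, 128 without hd/hd B, 251 without the +/+ array and 645 without the hd/+ array.

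**Figure D1:**
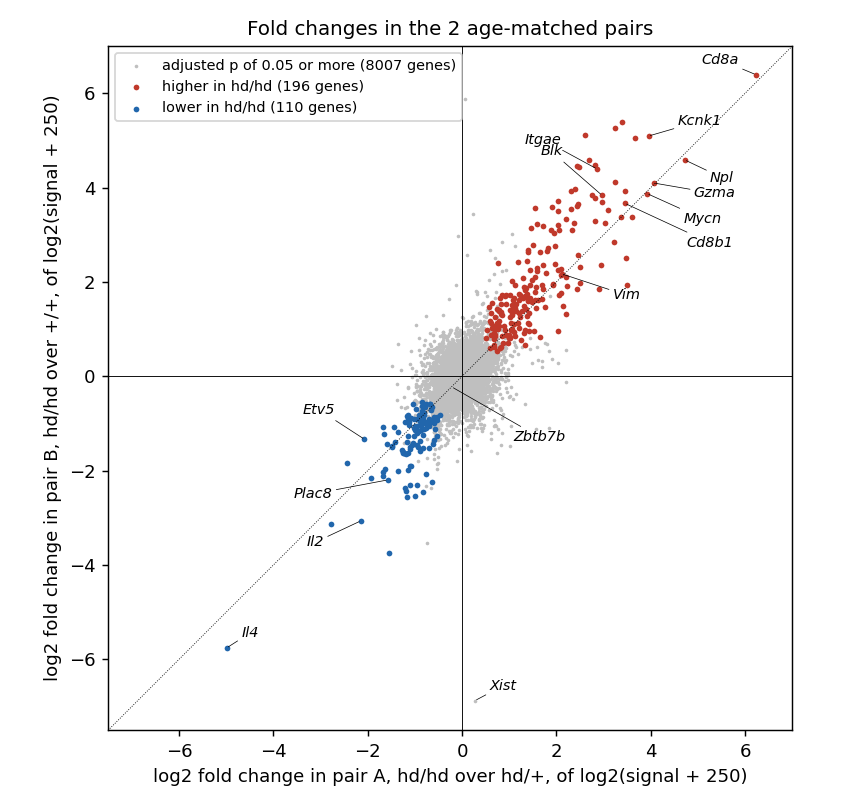
Each point is 1 of 8313 genes, with its log2 fold change of log2(signal + 250) in pair A (hd/hd over hd/+, x axis) and in pair B (hd/hd over +/+, y axis). The dotted line marks equal change, and colours show the 196 genes higher and 110 lower in hd/hd at a limma adjusted p under 0.05. Cd8a lies at the upper right and Il4 at the lower left, while Xist, at −6.87 in pair B and 0.27 in pair A, did not pass the test.

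Genes of the NKT17 and Th17 programme formed the group with the most changes. Of 22 measured members 16 rose, 0 fell and 6 did not pass the test, with a median log2 fold change of 2.09, in pair A 1.84 and in pair B 2.29. Il17re, a subunit of the receptor for IL-17C, rose 10.1-fold from 1294 ± 663 to 14573 ± 1267 (SD, n = 2; limma adjusted p = 0.000489). Another kept probe set of Il17re rose less, by log2 1.47 (limma adjusted p = 0.0555 among probe sets). Blk, a tyrosine kinase of the Src family, rose by 3.40 ± 0.31 on the log2 scale, Ltb4r1, the leukotriene B4 receptor BLT1, by 2.40 ± 0.20, and Nrp1, neuropilin-1, by 2.18 ± 0.20. The chemokine receptor gene Ccr6 (log2 2.80 ± 0.34, adjusted p = 0.00259) and the interleukin-1 receptor gene Il1r1 (4.25 ± 0.58, 3.44 to 5.01 over the pseudocounts tried, adjusted p = 0.00429) rose as well. Outside the lists, Ret, a receptor tyrosine kinase (log2 4.39 ± 0.50, 3.41 to 5.49 over the pseudocounts tried), Arg1, arginase (3.14 ± 0.30), Cd83 (2.99 ± 0.31) and Epas1, the hypoxia-inducible factor HIF-2α (2.16 ± 0.19), also rose, and Anxa1, annexin A1, fell by 1.28 ± 0.18 and the efflux pump gene Abcb1a by 0.98 ± 0.14 (limma adjusted p at most 0.00474). Il17a was at background on each array, at 324.4 and 236.0 in hd/hd, 401.0 in hd/+ and 279.8 in +/+, and the labels name no stimulation of the cells. Adjusted over the list alone, 18 members were higher and 1 lower. Camera placed the list above other genes (adjusted p = 1.99e-22), but with adjusted p = 0.375 with an estimated correlation, and fry gave an adjusted p of 0.102. Of the 6 measured γδ T cell markers, Blk, Cd163l1 (log2 2.41 ± 0.34) and Sox13 (2.15 ± 0.33) rose, all of them members of the NKT17 list too. Etv5, an ETS family factor of γδ T cells, fell by 1.70 ± 0.23 (limma adjusted p = 0.00408). This list had a median of 1.44 (camera adjusted p = 0.00495, adjusted p = 0.375 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone), and of 0.73 with the signal filter at the trimmed mean, which ended its call (adjusted p = 0.0538). Of the 4 fits that left out 1 array, Sox13 lost its call in 2, and Cd163l1, Anxa1 and Abcb1a in 1 each.

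**Figure D2:**
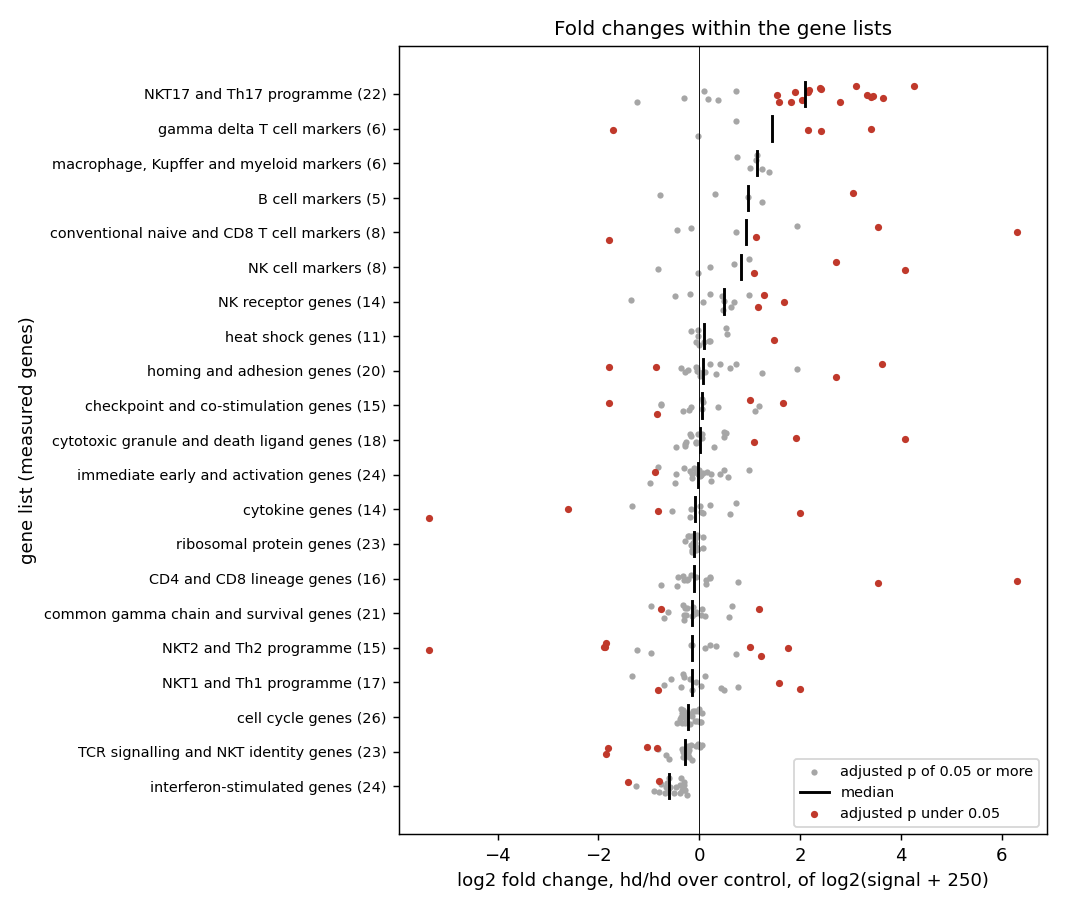
Points are measured genes of the 21 tested gene lists, placed by log2 fold change of hd/hd over control (x axis), with a black bar at each list's median and vertical scatter added for visibility only. Red points have a limma adjusted p under 0.05. The NKT17 and Th17 list has the highest median (2.09) and the interferon-stimulated genes the lowest (−0.59).

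Il4, the cytokine that NKT cells store as mRNA at rest, fell to near background in hd/hd cells. Its signal was 398.6 and 401.3 on the hd/hd arrays against 20301 in hd/+ and 34908 in +/+, so that Il4 fell by 5.37 ± 0.24 on the log2(signal + 250) scale (limma adjusted p = 2.36e-05; −4.57 to −5.89 over the pseudocounts tried). Il2 fell by 2.61 ± 0.51 (adjusted p = 0.025; −1.71 to −3.61 over the pseudocounts tried) and Ifng, the cytokine of type 1 responses, by 0.81 ± 0.18 (adjusted p = 0.0446), from 23330 ± 4144 to 13218 ± 2332 (SD, n = 2). The chemokine gene Ccl4 rose 4.03-fold (log2 2.01 ± 0.26, adjusted p = 0.0033). Of the 14 measured cytokine genes 1 rose, 3 fell and 10 did not pass, with a median of −0.07 (camera adjusted p = 0.212; 3 higher and 4 lower adjusted over the list alone). Of the 15 NKT2 and Th2 genes, Il4, Plac8, Slamf6 and Izumo1r fell, Icos, Ikzf2 and Nfil3 rose, and 8 did not pass. Plac8 fell by 1.89 ± 0.23 and Izumo1r, folate receptor 4, by 1.86 ± 0.29. The median of that list was −0.14 (camera adjusted p = 0.158; 4 higher and 6 lower adjusted over the list alone). Zbtb16, which encodes the NKT lineage factor PLZF, had signals of 11409 ± 462 in hd/hd and 12579 ± 141 in controls (SD, n = 2; log2 −0.14 ± 0.13, limma adjusted p = 0.762). Of the 17 NKT1 and Th1 genes, Ccl4 and Il18r1 (log2 1.59 ± 0.36, adjusted p = 0.0477) rose, Ifng fell and 14 did not pass, among them Xcl1 (−1.33 ± 0.31, adjusted p = 0.0533) and Tbx21, the gene of the type 1 factor T-bet (−0.31 ± 0.17, adjusted p = 0.48). This list had a median of −0.14 and a mean of 0.04, which differ in sign, with medians of −0.08 to −0.23 when 1 array was left out (−0.08 without +/+, −0.23 without hd/hd B), and no camera shift (adjusted p = 0.829; 5 higher and 4 lower adjusted over the list alone). The calls of Ifng, Il18r1, Il2 and Icos were lost in 3 of the 4 fits that left out 1 array, and that of Izumo1r in 1.

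Genes of cytotoxic granules rose in part. Gzma, the serine protease granzyme A, went from 5355 ± 2367 to 94256 ± 38650 (SD, n = 2), or 16.9-fold (log2 4.08 ± 0.33, limma adjusted p = 0.000489). Gzmm, granzyme M (log2 1.93 ± 0.28, adjusted p = 0.00545), and Prf1, perforin (1.09 ± 0.23, adjusted p = 0.0377), rose too. The other 15 of 18 measured members did not pass, Lamp2 for example at 0.50 ± 0.15 (adjusted p = 0.119). The list's median was 0.02 (camera adjusted p = 0.049, adjusted p = 0.433 with an estimated correlation; 5 higher and 0 lower adjusted over the list alone), and its call ended without the hd/+ array (median −0.13, adjusted p = 0.16) and at the smaller pseudocount (0.0551). Of 14 NK receptor genes, Klrb1b (log2 1.69 ± 0.20), Cd244a (1.16 ± 0.23) and Klra7 (1.28 ± 0.26) rose, 0 fell and 11 did not pass, with a median of 0.49. The inhibitory receptor gene Klrg1 was at −1.36 ± 0.38 (limma adjusted p = 0.0991). The NK receptor list passed camera (adjusted p = 0.000937, adjusted p = 0.375 with an estimated correlation; 7 higher and 1 lower adjusted over the list alone). The Klra7 probe set is of a type that can bind transcripts of related Ly49 genes. Of the 8 NK cell markers Gzma, Prf1 and S1pr5, a sphingosine phosphate receptor (log2 2.71 ± 0.28), rose and 5 did not pass, such as Irf8 (−0.82 ± 0.24, adjusted p = 0.127). Their median was 0.84 (camera adjusted p = 0.000542, adjusted p = 0.375 with an estimated correlation; 5 higher and 1 lower adjusted over the list alone). Without the hd/+ array the medians were 1.28 for NK cell markers and 0.82 for NK receptor genes, and without the +/+ array 0.33 and 0.30. Leaving out 1 array ended the calls of Prf1, Cd244a and Klra7 in 2 of the 4 fits and that of Gzmm in 1.

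Several surface receptors that modulate T cell activation were lower in hd/hd cells, while CD3 and core signalling genes did not pass the test. Of 23 genes of TCR signalling and NKT identity, the SLAM family receptors Slamf6 (log2 −1.84 ± 0.25) and Slamf1 (−1.82 ± 0.30), Cd6 (−1.04 ± 0.18) and the costimulatory receptor Cd28 (−0.84 ± 0.16) fell, 0 rose and 19 did not pass. The median was −0.27, with 21 of the 23 members below 0 (camera adjusted p = 2.58e-06, adjusted p = 0.443 with an estimated correlation; 0 higher and 7 lower adjusted over the list alone). It was −0.42 without the hd/+ array and −0.18 without hd/hd A. Of 15 checkpoint and co-stimulation genes, Nt5e, the ectonucleotidase CD73 (log2 1.66 ± 0.21), and Icos (1.01 ± 0.22) rose, and Btla (−1.80 ± 0.19) and Cd28 fell. Here the median was 0.06, and −0.01 to −0.17 with 1 array left out, while camera leaned downward (adjusted p = 0.859; 4 higher and 3 lower adjusted over the list alone). Of 21 common gamma chain and survival genes, Il7r, the IL-7 receptor, rose 2.29-fold, from 51129 ± 62.1 to 118040 ± 15910 (SD, n = 2; limma adjusted p = 0.0103). Bcl2, an antiapoptotic gene downstream of IL-7, fell by 0.75 ± 0.16 (adjusted p = 0.0367), and 19 did not pass, with Il4ra at −0.96 ± 0.22 and Socs3 at 0.65 ± 0.16 (median −0.14, −0.23 without hd/hd B or without the +/+ array, camera adjusted p = 0.122; 2 higher and 4 lower adjusted over the list alone). Over the kept Bcl2 probe sets, log2 changes ran from −0.26 to −0.75. Of 20 homing and adhesion genes, S1pr5 and Itgae rose, the latter encoding the αE integrin CD103 (log2 3.63 ± 0.42, 2.99 to 4.06 over the pseudocounts tried, adjusted p = 0.00229). Ccr9, a gut-homing chemokine receptor (−1.78 ± 0.28), and Itgb1 (−0.85 ± 0.17) fell, and 16 did not pass. Another kept Itgb1 probe set was at −0.12 (limma adjusted p = 0.931 among probe sets). The homing list had a median of 0.07 (camera adjusted p = 0.049, adjusted p = 0.433 with an estimated correlation; 7 higher and 2 lower adjusted over the list alone), and its call ended without the hd/+ array (median −0.02, adjusted p = 0.13), without hd/hd B (−0.003, 0.0706) and at the smaller pseudocount (0.0551). Of the 4 fits that left out 1 array, Itgb1, Bcl2 and Icos lost their calls in 3, Cd28, Il7r and Ccr9 in 2, and Slamf1 and Cd6 in 1.

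Interferon-stimulated genes were lower in hd/hd as a group by the preset camera test (adjusted p = 1.45e-11), but with adjusted p = 0.443 with an estimated correlation and 0.174 by fry. All 24 measured members had fold changes below 0, with a median of −0.59. Ifit2 (log2 −0.80 ± 0.15, limma adjusted p = 0.0178) and the RNA sensor gene Ifih1 (−1.42 ± 0.27, adjusted p = 0.0234) fell, and 22 did not pass one by one, Usp18 at −1.251 ± 0.30 and Zbp1 at −0.65 ± 0.16. Adjusted over the list alone, 0 were higher and 14 lower. Medians were −0.19 in pair A and −0.86 in pair B, and −0.38 without the +/+ array. With 1 array left out, Ifit2 lost its call in 3 of the 4 fits, and Ifih1 and the phosphatase gene Dusp2 in 2. Of 11 heat shock genes Hsph1 rose (2.81-fold, log2 1.49 ± 0.19, adjusted p = 0.00285), while Hspd1, Dnaja1 and Hspe1, at 0.53, 0.56 and 0.20, did not pass. The heat shock list had a median of 0.11 (camera adjusted p = 0.049, adjusted p = 0.479 with an estimated correlation; 2 higher and 0 lower adjusted over the list alone). Its call ended in 3 of the 4 fits that left out 1 array (adjusted p = 0.0653 without hd/+, 0.273 without hd/hd B, where the median was −0.06, and 0.118 without +/+) and at the smaller pseudocount (0.0528). Of 24 immediate early and activation genes Dusp2, whose product acts on MAP kinases, fell by 0.87 ± 0.14 (adjusted p = 0.0105) and 23 did not pass, such as Fos (0.98 ± 0.27), Egr2 (−0.82 ± 0.24) and Egr3 (−0.97 ± 0.30). Their median was −0.02 (camera adjusted p = 0.489; 0 higher and 1 lower adjusted over the list alone). None of the 26 cell cycle genes passed the limma test, over all genes or adjusted over the list alone. Mcm6 (−0.33 ± 0.14), Mcm2 (−0.30 ± 0.15), Pcna (−0.35 ± 0.21) and Cenpa (−0.35 ± 0.25) had the smallest p, and the list's median was −0.22 (camera adjusted p = 0.071). It was 0.32 in pair A and −0.86 in pair B, and leaving out 1 hd/hd array gave opposite camera calls, downward without hd/hd A (−0.74, adjusted p = 3.75e-17) and upward without hd/hd B (0.40, adjusted p = 8.36e-06). Of the 23 ribosomal protein genes none passed either way of adjustment, with Rps4x at −0.28 ± 0.28, Rpl8 at −0.20 ± 0.27, Rps24 at −0.23 ± 0.32 and Rpl37 at −0.13 ± 0.22 (median −0.11, camera adjusted p = 0.434).

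Markers of other liver cells were measured to show what else the sorts may have held. Of 8 conventional naive and CD8 T cell markers, Cd8a, Cd8b1 and Actn1 (log2 1.14 ± 0.24) rose, Ccr9 fell and 4 did not pass (median 0.93, 0.46 with no filter, camera adjusted p = 0.00127, adjusted p = 0.375 with an estimated correlation; 5 higher and 2 lower adjusted over the list alone). This was the list that also passed fry (adjusted p = 0.0141), with Cd8a and Cd8b1 among its genes. Its 9 other markers had a median log2 fold change of 0.452 (standard error 0.44 across genes) with no filter. Of 5 B cell markers Cd79b, part of the B cell receptor complex, rose from 414.3 ± 178 to 5146 ± 231 (SD, n = 2; log2 3.05 ± 0.25, limma adjusted p = 0.000489). Its partner Cd79a was at background, at 19.3 and 183.4 in hd/hd. Igha, the constant region of immunoglobulin A, fell by 2.96 ± 0.45 (limma adjusted p = 0.0073). Ighm (−0.78 ± 0.23), H2-Ab1 (1.247 ± 0.56) and H2-Aa (0.97 ± 0.54) did not pass, and the B cell list missed the threshold (median 0.97, camera adjusted p = 0.0521; 1 higher and 1 lower adjusted over the list alone). Its median was 0.02 with no filter, −0.02 without hd/hd A and 1.96 without hd/hd B, where it passed (adjusted p = 0.00045). Myeloid transcripts were highest in hd/hd A. The 6 measured myeloid markers had a median log2 difference of 2.40 between hd/hd A and hd/hd B and of 1.04 between hd/+ and +/+, and Lyz2, lysozyme, had signals of 5299 in hd/hd A, 957 in hd/hd B, 1340 in hd/+ and 497 in +/+. None of the 6 passed the limma test, Ctss at 0.75 ± 0.18, C1qb at 1.39 ± 0.73 and Mpeg1 at 1.14 ± 0.61 among them. The list passed camera (median 1.14, adjusted p = 0.00498, adjusted p = 0.479 with an estimated correlation; 1 higher and 0 lower adjusted over the list alone), but not without hd/hd A, where its median was 0.06, or without the +/+ array, where it was 0.64. Lists with under 5 measured genes were not tested. Of the hepatocyte markers Apoe was measured (1.92 ± 0.67, limma adjusted p = 0.203), of the erythroid markers Tfrc (−0.35 ± 0.21, adjusted p = 0.539), and of the endothelial markers Eng (1.95 ± 0.27, adjusted p = 0.00463) and Stab2 (2.92 ± 0.47, adjusted p = 0.00957), which both rose. None of the 13 other endothelial and stellate markers, whose means lay below the filter, passed in a limma fit without it, with Stab1 highest at 1.16, Pecam1 at 0.16, Cdh5 at 0.36 and Kdr at −0.04. Of the 4 fits that left out 1 array, Actn1 lost its call in 3, Stab2 in 2 and Eng in 1.

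The age-matched pairs gave similar changes for the genes that moved most. Across the 8313 genes, fold changes of pair A and pair B had a Pearson correlation of 0.622 and a Spearman correlation of 0.312. Pearson's value was 0.269 without the 306 genes past the threshold. The 306 had clear changes, all alike in direction in both pairs, so leaving them out lowers the value by construction. The values are correlations across genes, which are not independent replicates. At least 2-fold higher in hd/hd were 193 genes in pair A and 245 in pair B, 144 of them shared, where independent lists would share 5.7. At least 2-fold lower were 72 and 179, with 45 shared against 1.6. The 4 genes that moved at least 2-fold in opposite ways were higher in pair A and lower in pair B. They were Cxcl10, Tnfrsf9, Tpx2 and Ube2c, named after their values were seen. The spread of fold changes was larger in pair B (SD 0.574) than in pair A (SD 0.445). The pools also differed in sex. Xist, transcribed from the inactive X chromosome of females, had signals of 43514 in hd/hd A, 413 in hd/hd B, 35941 in hd/+ and 77378 in +/+. The Y-linked gene Eif2s3y was at 11922, 15613, 11460 and 20.2 in the same order, and Kdm5d and Uty were also near background in +/+ alone. By these genes hd/hd A and hd/+ held cells of both sexes, hd/hd B of males and +/+ of females, so that sex was alike in pair A and opposite in pair B. For the hd/hd against control comparison, Xist (log2 −3.30 ± 1.48, limma adjusted p = 0.358) and Eif2s3y (2.97 ± 1.31, 0.35) did not pass the test. Neither did Kdm5d (1.84 ± 0.74, 0.289) and Uty (1.44 ± 0.66, 0.374). Their differences were large but so was the spread within each group. The male pool was hd/hd and the female pool a control, so genotype was partly confounded with sex.

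Within the controls, hd/+ differed from +/+ more than the hd/hd pools differed from each other. The log2 differences had an SD of 0.354 across genes between the controls and 0.303 between the hd/hd arrays. A total of 103 genes were at least 2-fold apart between the controls, 82 higher and 21 lower in hd/+. Between the hd/hd arrays there were 69, of which 62 were higher in A and 7 in B. The filter on the mean over arrays kept genes high in hd/hd alone, such as Ret, at 769.8 in hd/+ and 20.3 in +/+. Noise in such weak control signals may add to the difference between the controls, though genes weak in hd/hd alone were kept too. Across genes, the difference between the controls and that between the hd/hd arrays had a Pearson correlation of 0.034. The hd/+ array lay between +/+ and hd/hd for many of the genes past the threshold. Of the 196 higher genes, 152 had a higher signal in hd/+ than in +/+ (median log2 difference 0.36), and of the 110 lower genes 88 had a lower one (median −0.27). For the 22 NKT17 and Th17 genes the median was 0.59, with 16 above 0. Blk, for example, had signals of 9942 ± 952 in hd/hd (SD, n = 2), 1144 in hd/+ and 415 in +/+. Cd8a and Cd8b1 differed little between the controls, at 392.4 against 361.2 and at 452.3 against 397.8. With 1 array each, these differences have no test, and the hd/+ and +/+ arrays also differ in age-matched pair and in sex.

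**Figure D3:**
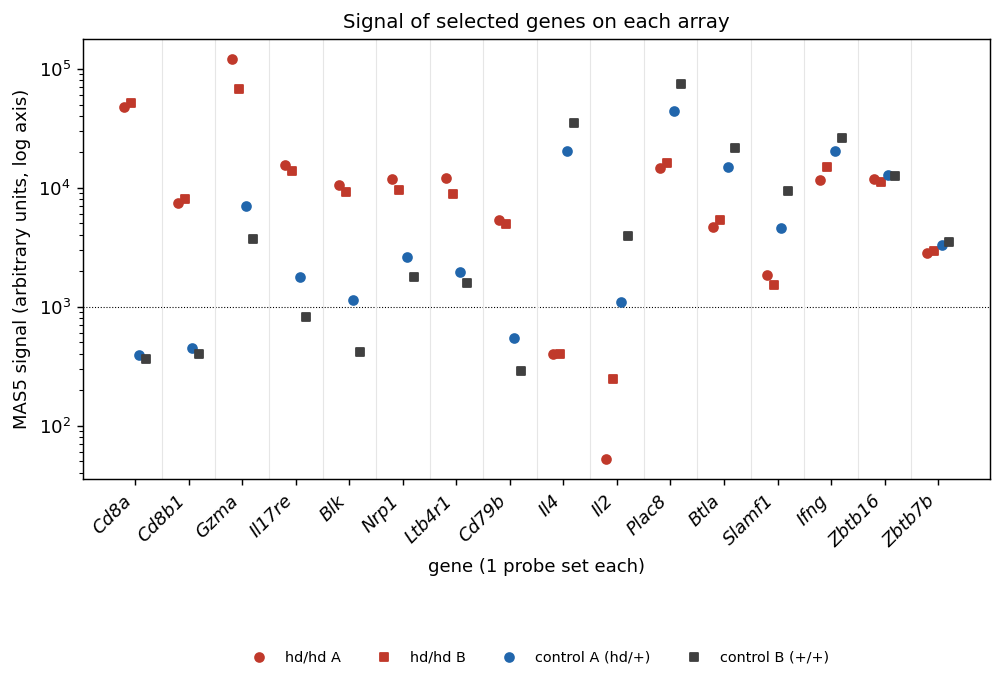
MAS5 signals (arbitrary units, log axis) of 16 genes on each of the 4 arrays, with red symbols for hd/hd, blue for hd/+ and dark grey for +/+, circles for pair A and squares for pair B. The dotted line is the signal of 1000 used as filter on the mean over arrays. For Il17re, Blk, Nrp1, Ltb4r1, Gzma and Cd79b the hd/+ symbol lies between those of +/+ and hd/hd, and for Cd8a both controls lie near 400.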

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

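The tests of Il4, of the hd/+ level and of sex were chosen after the results were seen, as was the margin of 1 standard error added to the bound of 0.5 in the tests of other lymphocytes. Standard errors of medians in this section were taken across genes as if genes were independent. They leave out variation between pools and are too small where genes move together. The cell cycle genes differed between the age-matched pairs, with a median log2 fold change of 0.319 in pair A, where 22 of 26 were above 0, and −0.861 in pair B, where 0 of 26 were. The hd/hd arrays differed by a median of 1.28 (A minus B) and the controls by −0.068 (hd/+ minus +/+). The difference was not tested, since each pair has 1 array per genotype. Of 1503 probe sets without a single gene name, which no comparison uses, 25 passed the limma threshold, 11 higher and 14 lower in hd/hd.

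Genes known from other lymphocytes were higher in hd/hd cells, among them Cd8a, Cd79b and Gzma. B cells were argued against, since the 15 other B cell markers had a median log2 fold change of 0.015 (standard error 0.202) and CD19 positive cells were depleted before the sort. Conventional CD8 T cells stayed open, with a median of 0.452 (standard error 0.44) over the 9 other naive and CD8 T cell markers, and so did NK cells, with 0.699 (standard error 0.334) over 12 other NK cell markers. The depletion of CD62L positive cells and the sort on the tetramer and TCR β would remove most such cells, but purity is not given. A change of expression within NKT cells themselves may account for these genes as well, a hypothesis that these arrays cannot separate from a mixture.

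Il4 fell by 5.37 on the log2 scale in hd/hd. Dilution of Il4-expressing cells by cells that lack T and NK cell genes was argued against. The 40 measured NKT1, Th1, TCR and identity genes had a median of −0.234 (standard error 0.14), where such dilution would need about the change of Il4. Many of these genes are shared with other T cells or NK cells, so the test cannot exclude dilution by those. A loss of 1 NKT subset rich in Il4, or loss of Il4 expression within cells, was not tested and stays open.

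For 240 of the 306 genes past the threshold, the hd/+ array lay toward hd/hd from +/+, with a median of 0.331 in that direction. Of 10000 random lists of similar mean expression, 0 went as far for the higher or the lower genes. These lists were matched on the mean over all arrays, not on the lower and noisier control signals of the higher genes. They also treat genes as independent, so they do not measure how often single pools would differ this way. Over the same genes hd/hd A differed from hd/hd B by a median of 0.024 (standard error 0.022) in that direction. For the higher genes this median was 0 against 0.359 between the controls. For these higher genes, this argues against a difference between the age-matched pairs that shifts their log2 signals alike in both genotypes. Genes with such a difference have a wider spread and pass the test without a block less readily, so genes that did not pass are not covered. The lower genes had 0.075 against 0.274, which leaves such a difference open for them. A difference that adds the same signal in both genotypes would hardly show at the high hd/hd signals of the higher genes, and stays open. Mixing of hd/hd RNA into the hd/+ pool was argued against as well, since Cd8a allows at most 1.06% where the median of 195 other higher genes would need 10.72% (standard error 1.25). A sex makeup acting alike in hd/hd and control cells predicted 0.111 between hd/hd B and hd/hd A over the 306 genes. The value seen was −0.024 (standard error 0.022), which likewise covers only genes that passed. A gene dose effect of the hd allele is 1 hypothesis, but sex acting in control cells alone and variation between pools, with 1 pool per genotype, stay open and untested.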

How the results depend on the processing

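The fits without genes over 2-fold apart in the hd/hd arrays (304 genes, a count that could hardly move since such genes have a wide spread) and with lists of 2 or more genes (12 lists) were chosen after seeing the data. The 306 genes became 131 with no filter (127 shared), 505 at an adjusted p under 0.1, and 179 at 2-fold in both pairs, the latter 2 by construction. Leaving out 1 array gave 122 to 645 genes (122 without hd/hd A, 128 without hd/hd B, 251 without +/+ and 645 without hd/+), with the lone array of a group assumed to vary like the others. The other settings without a block gave 204 (filter at the trimmed mean) to 425 (median centring). Of the 104 named genes 68 passed the threshold, 42 of them in each leave-one-out fit, and 0 of the 68 changed sign under any setting. Over the pseudocounts tried, log2 changes ran from 1.94 to 3.34 for S1pr5, 2.35 to 3.54 for Cd79b, 2.28 to 3.53 for Cd83, 2.08 to 3.80 for Stab2, 1.45 to 2.78 for Sox13 and −1.998 to −4.12 for Igha. The 11 lists became 6 with the filter at the trimmed mean (γδ T cell, cytotoxic, heat shock and homing lists among those lost) and 0 with an estimated correlation (smallest adjusted p = 0.375, 1 list at an unadjusted p under 0.05, 7 by fry), and 8 to 12 in the other settings without a block. The correlation of the pairs was 0.344 with no filter and 0.604 to 0.637 in the other settings. Of the lists past the threshold, medians turned sign for cytotoxic genes with no filter (−0.02) and the filter at the trimmed mean (−0.04). Over the leave-one-out fits medians ran from −0.134 to 0.199 for cytotoxic genes, −0.023 to 0.204 for homing genes (−0.003 without hd/hd B), −0.064 to 0.286 for heat shock genes and 0.055 to 2.331 for myeloid markers. Of the lists not past it, leave-one-out medians crossed 0 for cell cycle genes (−0.738 to 0.395), B cell markers (−0.016 to 1.957), ribosomal (−0.338 to 0.115), cytokine (−0.229 to 0.075), lineage (−0.181 to 0.013), NKT2 (−0.15 to 0.003) and immediate early genes (−0.073 to 0.014). They fell below 0 for checkpoint genes (−0.17 to −0.012, and −0.069 with the filter at the trimmed mean). The cause was not tested. The 3 splits of the 4 arrays are too few for a share under 0.05, and gave 306 genes for the real split and 0 at most for the others (177 at an unadjusted p under 0.05 against 1198). Each group of the other splits held 1 hd/hd and 1 control array, which puts the genotype difference into the spread. Their low counts are thus no reference for the 306. Genes with a mean signal under 1000, among them Cd4, were left out of the tests even where single arrays were higher, as for Cd4 in +/+.

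With the age-matched pair as a replicate block, a paired fit, 445 genes passed, all 306 shared, and 13 lists, the B cell and cell cycle lists being added. Of the named genes, 14 passed in addition, among them Lyz2, Ctss, Apoe, H2-Ab1, Runx3 and Xcl1. The labels name no shared litter, day or batch, and over all genes same-letter deviations of the pools from their group means had a correlation of 0.034, though myeloid markers were higher in A than in B in both groups (medians 1.042 and 2.398).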

Other observations

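The values in this part were chosen after they were seen, and none of these genes passed a limma test. NK cell transcripts below the signal filter were Ncr1, an activating NK receptor, at 1448.8 and 1086.6 on the hd/hd arrays, 407.9 in hd/+ and 211.3 in +/+ (adjusted p = 0.251 with no filter), and Klra8, at 806.8, 813.6, 345.8 and 171.6 (0.429). Eomes, a factor of NK and memory CD8 cells, was at 480.1, 325.6, 23.6 and 323.1 (0.761). Ms4a1, a B cell marker, was at 267.0, 84.7, 104.6 and 32.8 (0.825). The second Cd4 probe set was at 50.5, 19.0, 59.9 and 279.1, and that of Zbtb7b at 1745.6, 1553.7, 2368.0 and 1819.1 (adjusted p = 0.733 among probe sets). Csf1r, a macrophage receptor, was at 8137.7 in hd/hd A and 574.5 in hd/hd B, 1809.5 in hd/+ and 429.9 in +/+ (adjusted p = 0.681), and is 1 of the 6 measured myeloid markers.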
